A study of Mus musculus with 15 samples.

How the data were processed

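Total RNA from the hypothalamus of CD-1 mice on postnatal day 15 was sequenced in 15 samples, 3 in each of the groups Control, PGM, PGF, HM and HF, which were assigned from the sample titles. The deposited table held 1 value per transcript and group for 49404 transcripts with UCSC known gene identifiers and gene names. The values were RPKM that the authors had averaged over the samples of each group, per the file headers, and they were rounded to 2 decimals. Each column carried the name of its group, and which of the group's samples entered the mean is not given in the sources used here. Read quality was checked with FastQC and reads were aligned with Novoalign 2.08 to the mouse build mm10, per the submitters' processing notes. The program that counted reads, its handling of reads shared by isoforms, by near-identical genes or by strands, and the read depth are not given in the sources used here. Values of close paralogs such as the globins Hbb-b1 and Beta-s or the gamma crystallins, and of the antisense pair Xist and Tsix, are therefore uncertain as single genes. Smcy and Kdm5d are names of the same gene that the table lists apart.

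RPKM divides by transcript length and by the mapped reads of a library, so a gene's value also depends on what the other genes take, and an average over samples hides any sample that stands apart. Values per library were not used, so no test, SD or pairing of samples could be computed, and in place of limma and camera the plan for a table of means was followed, a description of differences with no test. Depth is unknown, so no interval is given. Where a group was at exactly 0 a gene is said to be listed at 0 and has no fold.

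Transcripts were reduced to the median per gene name, which gave 24831 names, 11394 of them with more than 1 transcript. Genes with a mean of at least 1 RPKM over the 5 groups were kept, 17481 or 70.4% of the names. The authors' scaling was kept. Differences were taken between values of log2(mean RPKM + 0.5). A fold is on that scale and understates the difference of genes with low values. A gene was counted at 1.5-fold, and there were 6 comparisons, each of 4 groups against Control, PGM against PGF and HM against HF. Positions come from GENCODE M21 (GRCm38, the assembly called mm10) by gene symbol, and 18084 names or 72.8% matched.

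Genes were named by a rule. It took the 12 genes with the largest difference in each direction, 6 for the comparisons between groups other than Control, among genes with at least 2 RPKM in 1 of the groups compared, leaving out names that carry no function, such as Riken clones. It added 18 neuropeptide and thyroid hormone genes and 4 members with the largest difference of each called list. Some genes that the rule takes are not reported here. Members were printed only where their list mattered to the comparison, a selection made afterwards, and genes given as examples outside the rule were chosen after their values were seen. The 34 gene lists covered thyroid hormone, hypothalamic neurons, cell types of the brain and of adjoining tissues, and general processes, and 33 had at least 3 measured members. Of the listed names 7 were found through a synonym and 3 were not found. For each list and comparison the median difference was placed among 10000 random lists of the same size matched in 20 bins of mean expression, and it was called when its percentile was under 2.5 or over 97.5. Of 132 such placements against Control, 87 or 65.9% were called, where 5% would be if genes were independent. Genes that vary together widen the true range, so a call describes these group means only.

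The calculations were tested on simulated data made from the Control values with known differences for PGM against Control over 17324 genes. Counting at 1.5-fold found 48 of 50 genes set at 2-fold, 49 of 49 at 4-fold, 49 of 49 at 8-fold, 0 of 49 at 1.25-fold and 0 of 17127 unchanged genes. Of 100 random lists of 15 unchanged genes 2 were called, and of 100 lists shifted by 0.3 all 100 were. The simulation assumed a small error for each mean and says nothing about the true error of these groups.

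The groups, the comparisons, the gene lists, the naming rule, the filter, the pseudocount, the threshold and part of the alternatives (pseudocounts of 0.1 and 1, no filter or a mean of at least 3 RPKM, upper quartile scaling, quantile normalization for the numbers of genes, and a 2-fold threshold) were fixed before the data were examined. The median over transcripts and the limits of the percentile were chosen once the table was seen. The alternatives added afterwards are named with their results. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.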

Results

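The series measured total RNA by sequencing in the hypothalamus of CD-1 mice, an outbred stock, on postnatal day 15, and its title concerns effects of thyroid hormone that reach the F2 generation. The 15 samples fell into 5 groups of 3 named Control, PGM, PGF, HM and HF, and the codes are used as the labels give them. The values were the authors' deposited mean RPKM (reads per kilobase of transcript, scaled to mapped reads) of each transcript in each group. No value per library was used, so no difference has a replicate check, no p-value or SD is given, and the sequencing depth is unknown. After transcripts were reduced to their median per gene name, 17481 of 24831 gene names had a mean of at least 1 RPKM over the 5 groups, and the median of these genes lay between 18.4 and 19.1 RPKM in every group. Differences are given as log2(mean RPKM + 0.5) of a group minus that of its reference, and a gene was counted when this reached 1.5-fold. A gene list is called higher or lower where its median lay outside the central 95% of random lists matched on expression. Over all kept genes the median difference from Control was 0.005 in PGM, -0.03 in PGF, -0.03 in HM and 0.02 in HF. It was 0.03 for PGM against PGF and -0.05 for HM against HF.

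The first comparison set PGM against Control and asked which hypothalamic transcripts differed in this group. Genes of myelin and mature oligodendrocytes were higher in PGM in 19 of 19 measured members, with a median difference of 0.62. Mal, a proteolipid of compact myelin, was at 311 RPKM against 159 in Control, Opalin at 61.4 against 32.4, and Mog, a surface glycoprotein of myelin, at 252 against 143. Mbp, which encodes myelin basic protein (chromosome 18, 82475146 to 82585637 in GRCm38), was at 4987 against 3228 RPKM, a difference of 0.63. Markers of oligodendrocyte precursors were lower in 6 of 8 members with a median of -0.19, among them Cspg4 at 19.8 against 25.6 RPKM.

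Markers of the thalamus, the structure above the hypothalamus, were higher in PGM in 8 of 8 members with a median of 1.07. Prkcd, a protein kinase C of thalamic relay neurons (chromosome 14, 30595354 to 30626210), was at 154 RPKM against 35.0 in Control, Ramp3 at 66.1 against 22.0, Synpo2 at 15.8 against 6.20 and Gbx2 at 19.5 against 7.87. Markers of cortex and striatum were higher in 8 of 12 members with a median of 0.45. They included Ppp1r1b, the striatal phosphatase inhibitor DARPP-32 (chromosome 11, 98348404 to 98357796), at 40.4 against 3.70 RPKM, the adenosine receptor gene Adora2a at 11.7 against 2.19, and Slc17a7, a vesicular glutamate transporter of cortical and thalamic neurons, at 53.9 against 20.2. Alongside these markers, Gabrd, an extrasynaptic GABA receptor subunit, was at 43.7 against 8.28 RPKM, Tnnt1 at 20.95 against 4.62 and Rab37 at 21.7 against 4.86.

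Genes that define hypothalamic neurons were lower in PGM while the thalamic and striatal markers were higher. The group means cannot tell lower expression in hypothalamic cells from a smaller share of hypothalamus in the samples, which was not tested. Transcription factors of hypothalamic development were lower in 21 of 23 members with a median of -0.25, including Otp (3.56 against 8.45 RPKM), Tbx3 (1.65 against 3.55), Sim1 (2.83 against 5.68) and Six6 (1.83 against 3.69). Neuropeptide and hypothalamic hormone genes were lower in 23 of 31 members with a median of -0.22. Avp, the vasopressin precursor (chromosome 2, 130580620 to 130582554), was at 352 against 658 RPKM, Oxt, the oxytocin precursor (chromosome 2, 130576173 to 130577054), at 288.7 against 503.6, and Agrp, an appetite-stimulating peptide of the arcuate nucleus, at 6.58 against 12.7. Kiss1, which acts upstream of the gonadotropin-releasing neurons, was at 1.19 against 2.90 RPKM, while Cck, abundant in thalamus and cortex, went the other way with 231 against 114. Receptors for energy signals were lower in 22 of 23 members with a median of -0.30, such as the leptin receptor Lepr (2.51 against 4.26 RPKM), the ghrelin receptor Ghsr (2.26 against 3.81) and Calcr (20.1 against 30.5).

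Among thyroid hormone genes in PGM, Trh, the releasing hormone that drives thyrotropin (chromosome 6, 92242061 to 92244650), was at 87.9 RPKM against 135 in Control, a difference of -0.62. Avp and Oxt were lower by more, at -0.90 and -0.80. The Trh difference therefore cannot be told apart from the lower level of hypothalamic genes in this group. Genes known to respond to thyroid hormone were higher in 8 of 10 members with a median of 0.31, and Mbp is also one of the myelin genes. Hr, a corepressor and direct target of the hormone (chromosome 14, 70552212 to 70573548), was at 32.7 against 22.0 RPKM, Sema7a at 34.7 against 23.2 and Klf9 at 123 against 101. Against Control this response list was called higher in PGM, PGF and HM, where thalamic markers were also higher, and not in HF (median 0.05). Its difference therefore cannot be told apart from a different share of tissue in the samples, which was not tested. The list of thyroid hormone transporters, deiodinases, receptors and cofactors had a median of -0.09 and a mean of 0.01 and lay within the range of random lists. In it, the receptor genes Thra and Thrb differed by -0.03 and 0.17, the activating deiodinase gene Dio2 by 0.29 and the inactivating deiodinase gene Dio3, listed near 1 RPKM, by 0.30. Crym, which encodes a thyroid hormone binding protein that is also abundant in striatum and cortex, was at 21.2 against 4.83 RPKM.

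Genes of tissues around the brain also differed in PGM. Markers of the meninges were lower in 10 of 10 members with a median of -0.80, including Ogn (4.58 against 13.03 RPKM), Igf2 (58.5 against 122) and Slc6a13 (7.56 against 15.7). The erythroid list was lower in 4 of 4 members with a median of -0.90, and Alas2, the erythroid enzyme of heme synthesis, was at 13.3 against 30.5 RPKM. Markers of vessels were lower in 14 of 15 members with a median of -0.21. Ttr, the thyroxine carrier made by the choroid plexus (chromosome 18, 20665280 to 20674321), was at 106 against 7.01 RPKM, 14.2-fold higher, while the choroid plexus list of 9 genes had a median of 0.17, a call that was lost with HF as the reference in place of Control. The pituitary hormone list was not called in PGM, with a median of -0.16 and 3 of 6 members higher, and Cga, the common subunit of the pituitary glycoprotein hormones, was at 5.60 against 26.2 RPKM while Gh was at 59.7 against 39.8. Lens crystallin genes were among the lowest, with Cryge at 0.04 against 4.11 RPKM and Crygb and Crygc listed at 0 in PGM. Cryge was also at 0.04 RPKM in PGF and 0.07 in HF and listed at 0 in HM, so Control was the group that stood apart. The Y-linked genes Ddx3y (chromosome Y, 1260771 to 1286629) and Eif2s3y were at 30.4 and 27.5 RPKM against 2.52 and 2.0 in Control, and Xist, the noncoding RNA of the inactive X (X chromosome, 103460366 to 103483254), was at 14.2 against 44.0. The sex chromosome list had a median of 2.92 with 4 of 5 members higher. A different share of males in the averaged samples may account for these genes. It would then bear on every comparison with Control, since the Y-linked genes were higher in all 4 other groups.

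Differences in PGM ran through other lists too. Imprinted genes were lower in 27 of 31 members with a median of -0.28, with H19 at 2.93 against 7.18 RPKM and Mest at 87.8 against 174, while Meg3 was higher at 234 against 147. These levels do not show whether imprinting itself changed, here or in PGF and HM. The list shares 1 gene with the energy receptor list and 1 with the meninges list, both also lower in PGM. Whether it follows those lists was not tested. Enzymes that modify chromatin were lower in 24 of 32 members with a median of -0.15, including the histone demethylase gene Kdm6b at 5.32 against 8.91 RPKM. Immediate early genes had a median of -0.39 with 10 of 16 lower, and Fos was at 19.9 against 42.4 RPKM. Sex steroid receptors and their partners had a median of -0.22, which was not called with HF as the reference, and the estrogen receptor gene Esr1 was at 3.85 against 6.89 RPKM. Astrocyte markers had a median of -0.16 with Gfap at 145.9 against 243.7 RPKM, and receptors for glutamate and GABA a median of -0.09 with a mean of 0.03. Nuclear genes of oxidative phosphorylation were higher in 76 of 78 members with a median of 0.16, genes of cholesterol synthesis in 16 of 17 with 0.20, histone genes in 53 of 60 with 0.13, and circadian genes had a median of 0.13. Across all genes, 409 were at least 1.5-fold higher and 398 at least 1.5-fold lower in PGM, which is 4.62% of the genes compared. Of 33 gene lists, 23 were called, 10 higher and 13 lower.

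The comparison of PGF with Control opened with hormone genes of the pituitary gland, which lies against the hypothalamus. These were higher in 6 of 6 members with a median of 3.52. Gh, the growth hormone gene (chromosome 11, 106300271 to 106301865), was at 1363 RPKM against 39.8 in Control, the prolactin gene Prl at 55.9 against 0.90, Cga at 170.3 against 26.2 and the thyrotropin subunit gene Tshb at 32.3 against 2.07. Pomc, which is expressed both in pituitary cells and in arcuate neurons, was at 369.7 against 24.3 RPKM. Ttr was at 440.5 against 7.01 RPKM, 58.7-fold higher, with the choroid plexus list higher in 8 of 9 members at a median of 0.38. The group means cannot tell a difference in hypothalamic cells from a different amount of pituitary or choroid plexus tissue in the samples. They also hide whether 1 sample carried the difference, and neither was tested. The same holds for these genes in the other groups. Nor can the means tell lower hypothalamic genes, in any group, from a different share of neighbouring tissue in the samples. In the plot of sex-linked, pituitary and Ttr values, PGF stood apart from the other 4 groups for the pituitary genes and shared the high Y-linked level with PGM.

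**Figure D1:**
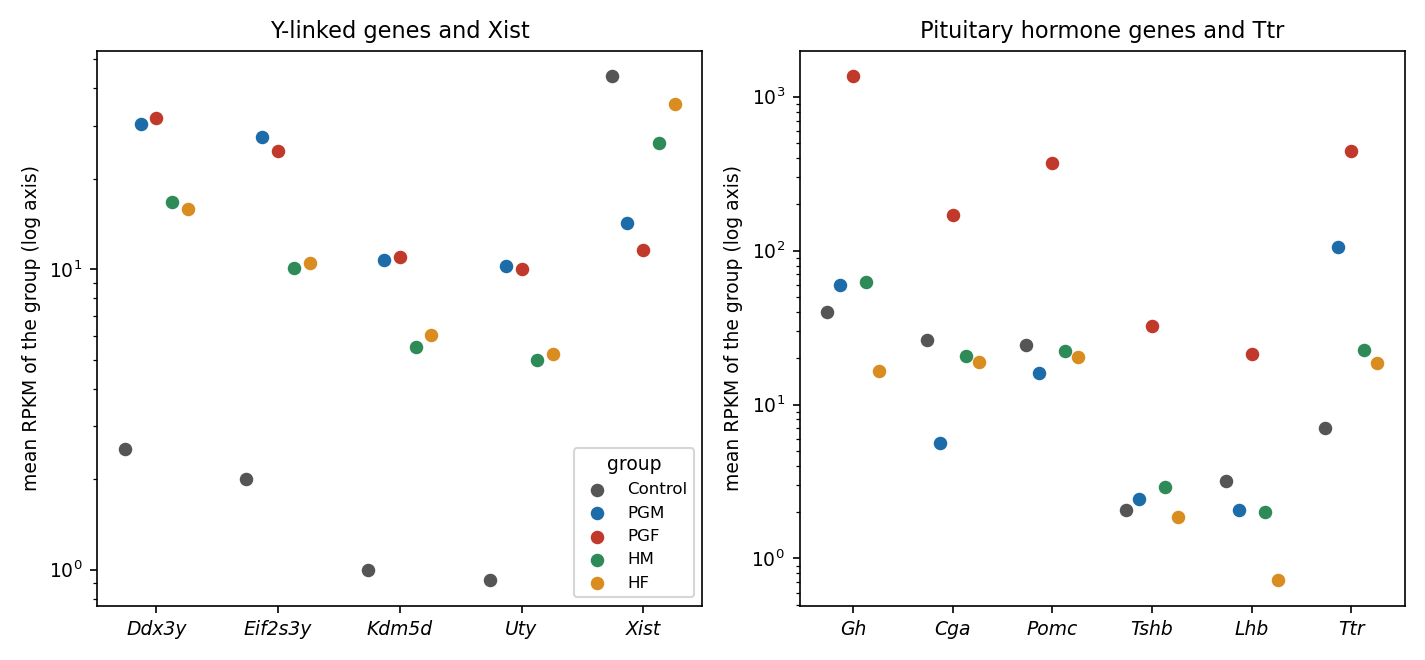
Mean RPKM of each group (log axis) for the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty with Xist on the left, and for Gh, Cga, Pomc, Tshb, Lhb and Ttr on the right, 1 point per group. Ddx3y was at 2.52 RPKM in Control and between 15.9 and 32.0 in the other groups, and Gh was at 1363 RPKM in PGF and at most 62.1 in the other groups.

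Myelin genes were higher in PGF in 19 of 19 members with a median of 0.92, including Mal at 425.5 against 159 RPKM, Mog at 337 against 143, Opalin at 76.5 against 32.4 and Mbp at 6448 against 3228. Oligodendrocyte precursor markers had a median of -0.07, within the range of random lists. Thalamic markers were higher in 8 of 8 members with a median of 0.74, with Prkcd at 156 against 35.0 RPKM and Ramp3 at 65.4 against 22.0, and markers of cortex and striatum in 7 of 12 with a median of 0.27, with Ppp1r1b at 19.2 against 3.70. Gabrd was at 42.2 against 8.28 RPKM beside them.

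Hypothalamic transcription factor genes were lower in PGF in 22 of 23 members with a median of -0.46, including Otp at 3.15 against 8.45 RPKM, Hmx3 at 1.56 against 4.23 and Nr5a1, which marks the ventromedial nucleus, at 2.71 against 5.41. Neuropeptide genes were lower in 25 of 31 members with a median of -0.29. Agrp was at 4.64 against 12.7 RPKM, Avp at 266.8 against 658, Oxt at 210.4 against 503.6, Kiss1 at 1.08 against 2.90, and Ghrh, the releasing hormone for growth hormone, at 5.96 against 10.9. Energy signal receptors were lower in 22 of 23 members with a median of -0.30, with Calcr at 18.2 against 30.5 RPKM and Cckar at 4.99 against 7.91.

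Trh was at 76.0 RPKM in PGF against 135 in Control, a difference of -0.83, and Dio2 at 23.5 against 14.5, a difference of 0.68. Avp and Oxt, at -1.30 and -1.26, were lower by more than Trh, so here too its difference cannot be told apart from that of other hypothalamic genes. Hr was at 31.1 against 22.0 RPKM and Sema7a at 36.8 against 23.2, and the thyroid hormone response list had a median of 0.12 with 6 of 10 members higher. The transporters, deiodinases, receptors and cofactors were lower in 13 of 20 members with a median of -0.14, including Trhr, the receptor gene for Trh, at 8.04 against 11.99 RPKM. Thra and Thrb differed by -0.15 and 0.11. Neither list was called with HF as the reference, with medians of 0.018 and -0.13.

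Markers of the meninges were lower in PGF in 9 of 10 members with a median of -0.43, with Ogn at 7.82 against 13.03 RPKM, and erythroid genes in 4 of 4 with a median of -0.47. Imprinted genes were lower in 28 of 31 members with a median of -0.34 (Mest 98.1 against 174 RPKM), and chromatin enzymes in 27 of 32 with a median of -0.18 (Kdm6b 4.39 against 8.91 RPKM). Oxidative phosphorylation genes were higher in 74 of 78 members with a median of 0.14 and cholesterol synthesis genes in 14 of 17 with 0.22. Glucocorticoid-responsive genes had a median of 0.15 and interferon-response genes 0.20. With HF as the reference in place of Control, the interferon list and the cortex and striatum list were called lower, with medians of -0.21 and -0.23, and the glucocorticoid list was not called, with -0.11. Ddx3y was at 32.0 against 2.52 RPKM and Xist at 11.6 against 44.0. Crystallin genes were lower, with Cryge at 0.04 against 4.11 RPKM and Crygc and Crygd listed at 0 in PGF. In PGF, 377 genes were at least 1.5-fold higher and 329 at least 1.5-fold lower (4.04%), and 21 lists were called, 11 higher and 10 lower.

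**Figure D2:**
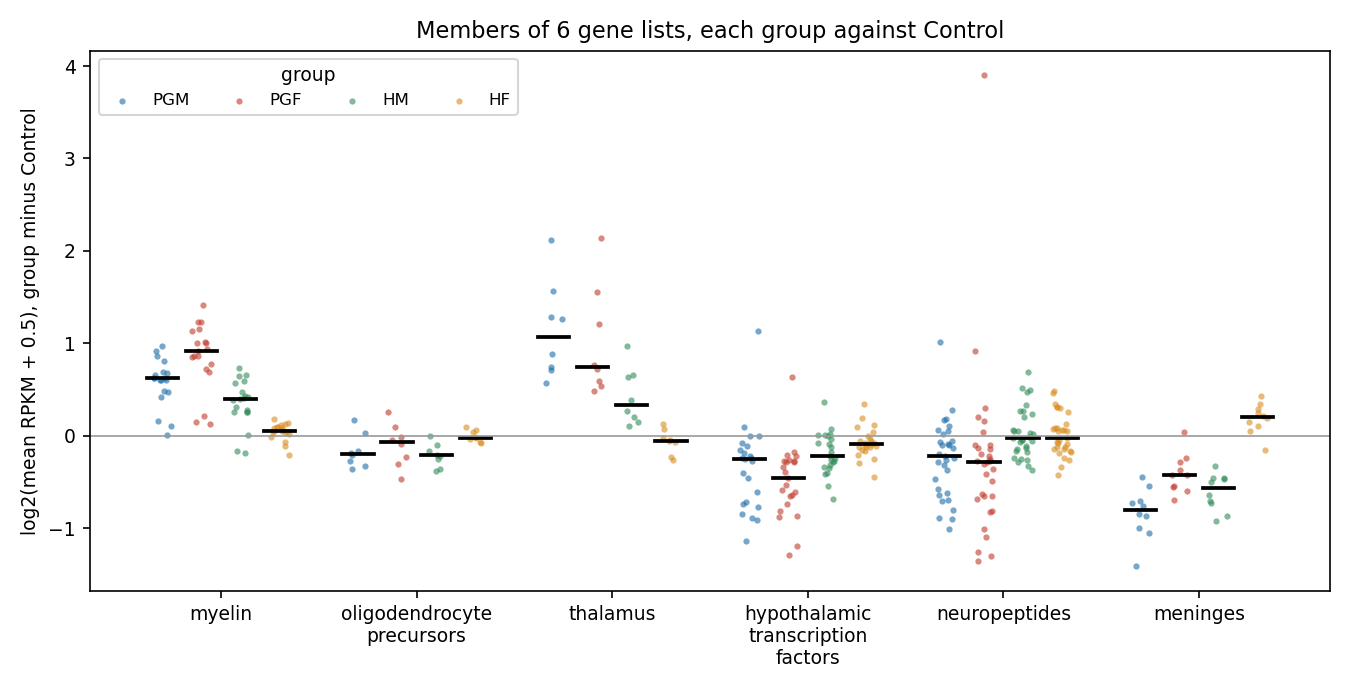
Log2 difference of each group from Control (vertical axis) for the members (points) and medians (black bars) of 6 gene lists, namely myelin, oligodendrocyte precursors, thalamus, hypothalamic transcription factors, neuropeptides and meninges, in PGM, PGF, HM and HF. The myelin medians were 0.62, 0.92, 0.40 and 0.05, and the medians of the hypothalamic transcription factors were -0.25, -0.46, -0.22 and -0.09.

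In HM, Cartpt, an appetite-suppressing peptide gene (chromosome 13, 99898489 to 99901091), was at 175 RPKM against 108 in Control, a difference of 0.69. Agrp was at 18.1 against 12.7 and Npy at 100.5 against 83.5, both under 1.5-fold, and Pomc at 22.4 against 24.3. Ucn, a peptide of the corticotropin-releasing family, was at 3.71 against 1.35 RPKM, and Crh itself at 10.6 against 9.19. The neuropeptide list as a whole had a median of -0.03 and a mean of 0.03, within the range of random lists, and Avp, Oxt and Trh differed by -0.33, -0.13 and -0.28.

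Myelin genes were higher in HM in 17 of 19 members with a median of 0.40, among them Mal at 265 against 159 RPKM, Ermn at 35.7 against 22.5 and Opalin at 51.3 against 32.4. Oligodendrocyte precursor markers were lower in 8 of 8 members with a median of -0.21, including Cspg4 at 19.9 against 25.6 RPKM. Thalamic markers were higher in 8 of 8 members with a median of 0.33 and Prkcd at 69.2 against 35.0 RPKM, while hypothalamic transcription factor genes were lower in 17 of 23 with a median of -0.22, including Otp at 5.07 against 8.45, Hmx3 at 3.06 against 4.23 and Lhx1 at 4.81 against 7.22. Ppp1r1b was at 13.4 against 3.70 RPKM and Gabrd at 17.5 against 8.28, with the cortex and striatum list at a median of 0.23.

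Glucocorticoid-responsive genes were higher in HM in 12 of 13 members with a median of 0.27. They included Zbtb16 at 16.7 against 9.54 RPKM, Fkbp5, a cochaperone of the glucocorticoid receptor, at 21.2 against 14.8, and Sult1a1 at 25.7 against 17.2. Genes that respond to thyroid hormone were higher in 7 of 10 members with a median of 0.22, with Hr at 28.9 against 22.0 RPKM and Itih3 at 110.9 against 80.7. Dio2 was at 21.6 against 14.5 RPKM, a difference of 0.56, and Klf9, Thra and Thrb differed by 0.06, -0.08 and 0.16.

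Erythroid genes were lower in HM in 4 of 4 members with a median of -1.21, with Alas2 at 11.7 against 30.5 RPKM and the globin gene Beta-s at 929.7 against 2156. Markers of the meninges were lower in 10 of 10 members with a median of -0.57, with Ogn at 6.61 against 13.03 RPKM and Slc22a6, an organic anion transporter gene, at 2.26 against 6.22. Vessel markers were lower in 12 of 15 members with a median of -0.21. Proliferation genes were lower in 12 of 14 members with a median of -0.27, including Mki67 at 1.70 against 2.58 RPKM. Imprinted genes were lower in 28 of 31 members with a median of -0.14 and chromatin enzymes in 27 of 32 with -0.11, with Kdm6b at 5.35 against 8.91 RPKM, and the call of the chromatin enzymes was lost with HF as the reference. Immediate early genes had a median of -0.19, histone genes -0.10 with 59 of 60 lower, ribosomal protein genes -0.04 with 64 of 80 lower, and heat shock and unfolded protein genes 0.12 with 14 of 15 higher. The ribosomal median lay near that of all kept genes in HM, -0.03. Ddx3y was at 16.8 against 2.52 RPKM and Xist at 26.4 against 44.0, with Ttr at 22.8 against 7.01. HM had 118 genes at least 1.5-fold higher and 151 at least 1.5-fold lower (1.54%), so 43.9% were higher, and 58.0% with quantile normalization (153 higher and 111 lower). At 2-fold, 25 genes were higher and 13 lower in HM. In it 22 lists were called, 10 higher and 12 lower. With HF as the reference, the transmitter identity list (0.06 against Control) was called lower with a median of -0.15. The tanycyte and ependyma list (0.14), the cortex and striatum list, the oxidative phosphorylation list (0.03) and the sex chromosome list (2.0) were then not called, with -0.013, -0.088, -0.047 and -0.060.

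In HF, Fggy, a carbohydrate kinase gene (chromosome 4, 95557507 to 95926939), was at 1.16 RPKM against 8.60 in Control and 8.79 in HM, and apart from crystallin genes no named gene was lower by more. Interferon-response genes were higher in 13 of 14 members with a median of 0.38, including Ifit1 at 2.30 against 0.88 RPKM, Irf7 at 2.33 against 1.27 and Ifitm3 at 23.6 against 15.4. Genes of transmitter identity were higher in 13 of 17 members with a median of 0.13. They included Slc6a3, the dopamine transporter gene (chromosome 13, 73536747 to 73578672), at 122.6 against 58.1 RPKM, and Th, the rate-limiting enzyme of dopamine synthesis, at 103 against 62.0. Glucocorticoid-responsive genes were higher in 11 of 13 members with a median of 0.23, including Plin4 at 2.90 against 1.67 RPKM and Sult1a1 at 22.6 against 17.2.

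The myelin list in HF had a median of 0.05 and lay within the range of random lists, with Mbp at 3440 against 3228 RPKM. Thalamic markers had a median of -0.06 with 6 of 8 lower, markers of cortex and striatum a median of 0.21 with Ppp1r1b at 13.9 against 3.70 RPKM, and hypothalamic transcription factor genes a median of -0.09 with 17 of 23 lower, including Otp at 6.05 against 8.45 RPKM. Neuropeptide genes were called lower with a median of only -0.02 and had a mean of 0.01, with Cartpt at 149.6 against 108 RPKM, Agrp at 16.2 against 12.7 and Crh at 11.5 against 9.19. Among thyroid hormone genes, Crym was at 13.9 against 4.83 RPKM, and Trh, Hr, Dio2, Thra and Thrb differed by -0.12, 0.13, 0.21, 0.03 and -0.04. The handling list was called lower with a median of only -0.04 and had a mean of 0.04.

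Meninges markers were higher in HF in 9 of 10 members with a median of 0.20, in contrast to the other groups, and erythroid genes lower in 4 of 4 with -0.23. Microglia markers had a median of 0.09 with 10 of 13 higher, tanycyte and ependyma markers 0.14 with 10 of 11 higher, ribosomal protein genes 0.06 with 76 of 80 higher and oxidative phosphorylation genes 0.08 with 73 of 78 higher. Pituitary hormone genes were lower in 6 of 6 members with a median of -1.21, with Gh at 16.5 against 39.8 RPKM, Lhb at 0.72 against 3.19 and Prl listed at 0. Ddx3y was at 15.9 against 2.52 RPKM and Xist at 35.4 against 44.0, and Cryge at 0.07 against 4.11. In HF, 115 genes were at least 1.5-fold higher and 30 at least 1.5-fold lower (0.829%), or 201 and 162 when genes with low values were not filtered out, and 21 lists were called, 10 higher and 11 lower.

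**Figure D3:**
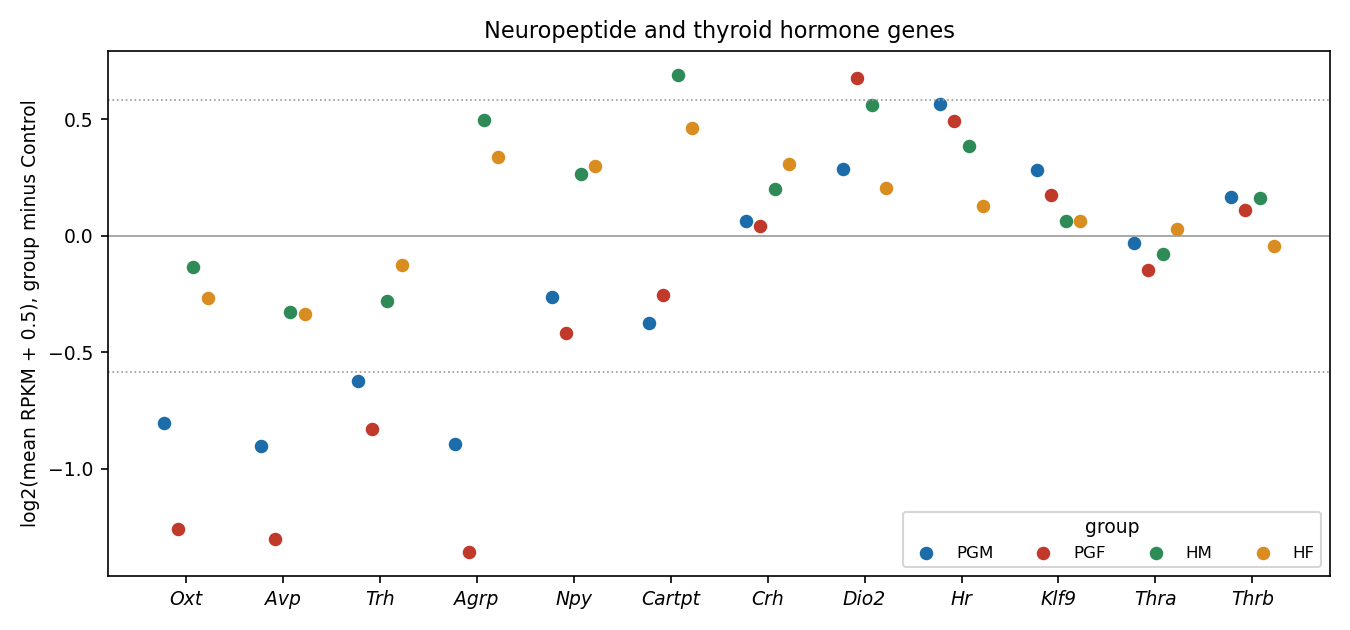
Log2 difference of PGM, PGF, HM and HF from Control (vertical axis, 1 point per group) for 12 neuropeptide and thyroid hormone genes, with dotted lines at 1.5-fold in each direction. Oxt, Avp, Trh and Agrp were lowest in PGF at -1.26, -1.30, -0.83 and -1.36, and Cartpt was highest in HM at 0.69.

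Set directly against PGF, PGM had much lower pituitary hormone genes, with 6 of 6 members lower and a median of -4.36, and lower choroid plexus genes, with 9 of 9 lower and a median of -0.49. Gh was at 59.7 RPKM in PGM against 1363 in PGF, and Pomc at 16.1 against 369.7. Crym was at 21.2 in PGM against 7.96 in PGF, Adora2a at 11.7 against 4.58 and Ppp1r1b at 40.4 against 19.2, all 3 genes abundant in striatum, and Gstt1 was at 14.6 against 6.26. Myelin genes were lower in PGM in 19 of 19 members with a median of -0.27, thalamic markers had a median of 0.12 with 6 of 8 higher, and meninges markers were lower in 10 of 10 with -0.42. The Y-linked genes were at like levels in both groups, with a median difference of -0.003. In all, 76 genes were at least 1.5-fold higher and 97 at least 1.5-fold lower in PGM.

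Set directly against HF, HM had lower Eln, Acta2 and Cnn1, genes of smooth muscle and elastic tissue. No planned list covered this theme, which was seen only in the values. Eln was at 15.9 RPKM in HM against 43.8 in HF, Acta2, the smooth muscle actin gene (chromosome 19, 34241090 to 34255590), at 17.2 against 45.3, and Cnn1, a contractile protein gene, was among the 6 lowest. Meninges markers were lower in HM in 10 of 10 members with a median of -0.78, and interferon-response genes in 14 of 14 with -0.44. Myelin genes were higher in HM in 18 of 19 members with a median of 0.33 and thalamic markers in 8 of 8 with 0.43, while the Y-linked median was -0.06. Fggy, Gh and Cdr1 were higher in HM by 2.49, 1.88 and 1.19. In HM, 64 genes were at least 1.5-fold higher and 229 lower, so 21.8% were higher, and 39.0% with quantile normalization (98 higher and 153 lower).

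Glo1, which encodes the enzyme that clears methylglyoxal, was picked out after its values were seen. It lies on the minus strand of chromosome 17 (30584936 to 30626871) and was at 148 RPKM in HF and 201 in HM against 295 in Control, differences of -0.996 and -0.55, while PGM and PGF were at 332 and 368. Its kept neighbours Zfand3, Btbd9 and Glp1r, the gene of the receptor for the peptide GLP1, differed in HF by -0.22, -0.30 and -0.38.

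**Figure D4:**
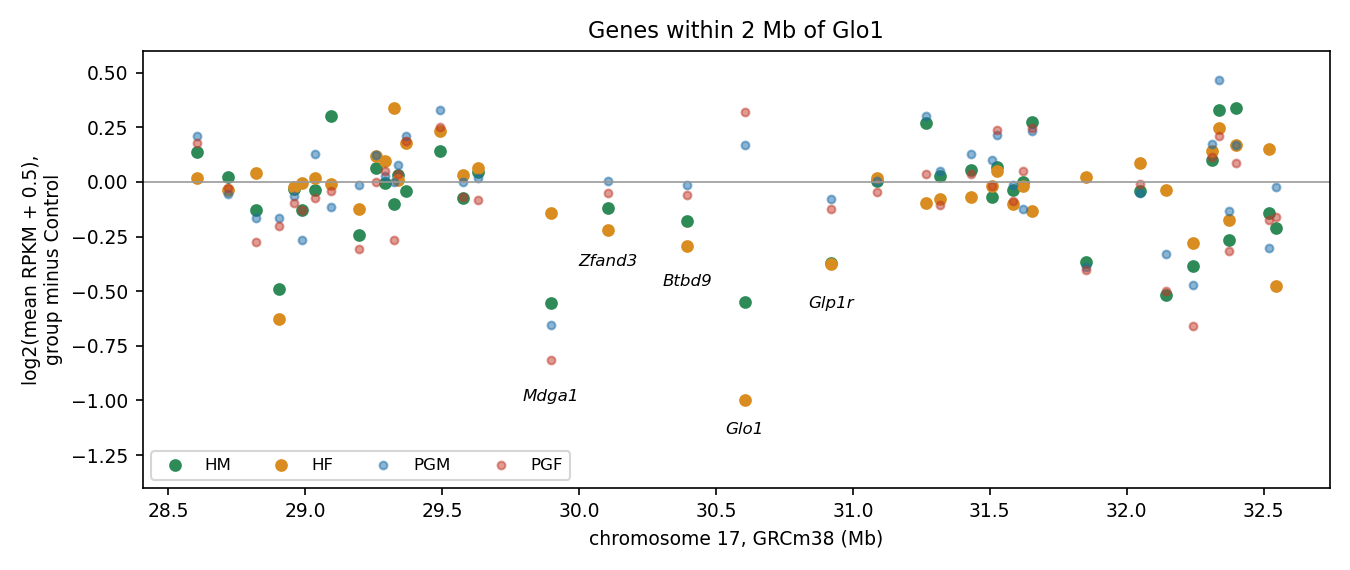
Log2 difference from Control (vertical axis) of the kept genes within 2 Mb of Glo1 against their position on chromosome 17 in GRCm38 (horizontal axis, Mb), 1 point per gene and group. Glo1 stood at -0.996 in HF and -0.55 in HM and above 0 in PGM and PGF.

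The groups' differences from Control were then compared with each other across genes, which are not independent replicates. The differences in PGM and PGF correlated with a Pearson r of 0.78 and a Spearman rho of 0.81 (covariance 0.0644), and 81.1% of genes had the same sign. The r was 0.73 for PGM with HM, 0.69 for PGF with HM, 0.49 for HM with HF, 0.45 for PGF with HF and 0.44 for PGM with HF. Of the genes at least 1.5-fold higher, 254 were shared by PGM and PGF where 8.82 would be shared by independent lists, and of those at least 1.5-fold lower 175 were shared where 7.49 would be. HM and HF shared 47 higher and 9 lower genes, and all 4 groups shared 35 higher and 4 lower. All these values use the same Control mean, whose true error could not be had without values per library. In simulated unchanged groups with the same error in each mean, differences from 1 reference correlated with an r of 0.50. The real differences were of unequal size, with 4.62%, 4.04%, 1.54% and 0.829% of genes at 1.5-fold in PGM, PGF, HM and HF. The simulated 0.50 may therefore not be the value for these pairs. How much of any r, or of the overlaps, comes from the shared Control cannot be told, and the lower values for HF cannot be read as agreement beyond it. With no group in common, differences of HM from HF correlated at 0.42 with those of PGM from Control and at 0.36 with those of PGF from Control. For PGM and PGF taken from 2 different references among Control, HM and HF, so that no group was in common, the r was 0.61, 0.59, 0.45, 0.42, 0.40 and 0.35 in the 6 pairs.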

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

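The alternatives chosen after the data were seen were the highest or the mean value over transcripts, functional gene names only, HF in place of Control, correlations with no or another shared group, and quantile normalization of the gene lists. No paired analysis was possible because the table held only group means. For the same reason a replicate block, leaving out a replicate, a fit of only 2 groups, other adjusted p-values, an estimated correlation or block in the list tests, and a test for any difference among the groups were not run. Counts of genes moved with the threshold and filter because fewer or more genes could be counted. At 2-fold they were 145 in PGM, 147 in PGF, 38 in HM, 54 in HF, 50 for PGM against PGF and 46 for HM against HF. Without a filter they were 496 in HM, 363 in HF, 388 for PGM against PGF and 520 for HM against HF, and with a mean of at least 3 RPKM 172, 75, 93 and 182. With functional names only, HF had 88 and PGM against PGF 97, and a pseudocount of 0.1 gave 271 for PGM against PGF, which adds weight to genes with low values. The correlation of PGM with PGF was 0.78 with Control shared by both, 0.61 for PGM from Control with PGF from HF, 0.59 for PGM from HF with PGF from Control, and 0.42 for PGM from HM with PGF from HF, and the cause was not tested. Of 87 called list results, 87 kept their direction and call under upper quartile scaling, 86 under quantile normalization, where ribosomal proteins in HM lost theirs at -0.02, and 85 with the highest transcript. With HF in place of Control, which applied to 66 results in PGM, PGF and HM, 52 kept their call, 11 were no longer called and 3 were called the other way, and the cause was not tested. Called the other way were transmitter identity in HM (-0.15) and cortex and striatum (-0.23) and interferon response (-0.21) in PGF. No longer called, and with the opposite sign, were tanycytes and ependyma (-0.013), cortex and striatum (-0.088), the sex chromosome list (-0.060) and oxidative phosphorylation (-0.047) in HM and glucocorticoid response (-0.11) in PGF. Those no longer called, with the same sign, were thyroid hormone response (0.018) and handling (-0.13) in PGF, steroid signalling (-0.19) and choroid plexus (0.094) in PGM, and glutamate and GABA receptors (-0.052) and chromatin enzymes (-0.088) in HM. Of 476 named-gene results, none of at least 1.5-fold changed sign in any setting run for single genes, and 33 moved with a pseudocount of 0.1 and 18 with 1, among them crystallin genes, Prl and Fshb, and 0 moved under either scaling or either other summary of transcripts. Depth is unknown, so the error of values near 0 cannot be bounded, and a difference in such genes rests on few reads or on none.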

Other observations

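All tests in this part, and the gene groups formed for it, were chosen only after the result was seen. A set of 6 contractile genes of smooth muscle and the elastin gene Eln was higher in HF than in Control in 7 of 7 members with a median log2 difference of 1.10, including Acta2 at 45.3 RPKM against 19.6, Myh11 at 8.86 against 3.69 and Tagln at 23.7 against 11.4, and lower in HM than in HF in 7 of 7 with -1.25. Genes of midbrain dopamine neurons were higher in 6 of 6 members in PGF, HM and HF, with medians of 0.47, 0.28 and 0.70, and lower in 6 of 6 in PGM with -0.34. Among them En1, a transcription factor of these neurons, was at 5.02 RPKM in HF against 2.13 in Control, and Slc6a3 at 109.6 in PGF, 76.9 in HM and 46.0 in PGM against 58.1. Striatal genes had medians of 1.39, 0.71, 0.41 and 0.58 in PGM, PGF, HM and HF, with 5 of 6 members higher in each.

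Of 33 Snora genes, which guide pseudouridylation, 28, 31, 30 and 30 were higher than in Control in PGM, PGF, HM and HF, with medians of 0.44, 0.78, 0.54 and 0.30. Of 42 Snord genes, which guide ribose methylation, 26, 33, 35 and 31 were higher, with medians of 0.21, 0.29, 0.26 and 0.24. The minor spliceosome RNAs Rnu11 and Rnu12 were at 994 and 985 RPKM in PGF against 204 and 191 in Control. A set of 8 lens genes, 7 crystallins and the filament gene Bfsp2, was lower than in Control in 8 of 8 members in every group, with medians of -2.29, -2.27, -2.19 and -2.11, but Bfsp2 differed by only -0.31 in HM and -0.22 in HF. Control had 33 genes at least 1.5-fold below every other group and 11 above, and PGF had 37 above and 7 below.

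Y-linked genes stood at 3 levels, with Kdm5d at 1.0 RPKM in Control, 5.49 and 6.03 in HM and HF, and 10.7 and 11.0 in PGM and PGF, while Xist and Tsix went the other way. A different share of male animals in the averaged samples may account for this, since X-linked genes that escape inactivation (Kdm6a, Eif2s3x, Kdm5c and Ddx3x) should then also be lower. They were, by a median of -0.27 in PGF with 4 of 4 lower, and with -0.19, -0.12 and -0.07 in PGM, HM and HF. The sex of the animals was not among the labels used here, and an effect of the labelled group on these genes stays open and was not tested. Any gene that differs between males and females can differ between these group means for that reason.

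Myelin genes were higher in PGF, PGM and HM while hypothalamic regulators were lower and thalamic markers higher. A larger share of thalamus in the dissected tissue is argued against as the whole cause of the difference between PGM and PGF only. There myelin genes were lower in PGM in 19 of 19 members (median -0.27) while thalamic markers had a median of 0.12, with 6 of 8 higher. Other comparisons go with it, with medians of 0.33 for myelin and 0.43 for thalamus in HM against HF. In HF against Control they were 0.05 and -0.06. A share of thalamus therefore stays open for the differences from Control. A different share of males stays open, since myelin was higher in HM than in HF in 18 of 19 members (0.33), where medians of -0.06 for Y-linked and -0.02 for X-linked escape genes speak against it, as does HF against Control with 2.13 for Y-linked and 0.05 for myelin genes, while Xist, which differed by -0.42 between HM and HF, goes with it. More cells of the whole oligodendrocyte lineage would raise precursor markers too, and these had medians of -0.070 in PGF, -0.19 in PGM and -0.21 in HM. More fibre tract in the dissection, a different stage of maturation and an effect of the labelled group may each remain, and none of these was tested. An effect of the group could include one through thyroid hormone, which promotes myelination.

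Glo1 was lower in HF and HM together with its neighbours. In HF it lay in a run of 4 adjacent kept genes, Zfand3, Btbd9, Glo1 and Glp1r, each lower by at least 0.2, but these limits were set after the values were seen, so the run decides nothing about its cause. Reads shared with copies of Glo1 alone would leave its neighbours unchanged, and Btbd9 was itself at -0.30. This value says nothing about the larger difference of Glo1, for which shared reads stay open. A difference in copy number or in regulation of the segment, which could vary among animals of an outbred stock, stays open, as does an effect of the labelled group, which was not tested.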
